A study of Caenorhabditis elegans with 6 samples.

How the data were processed

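Total RNA of starved L1 larvae was profiled on Affymetrix C. elegans Genome arrays, with 3 biological replicates of wild type and 3 of the hyl-1(ok976); lagr-1(gk327) double mutant. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, purified on columns, and 6 µg of total RNA gave the biotin-labelled cRNA for each array. Groups and replicate numbers were taken from the sample titles. The deposited table holds 1 value per probe set and array, for 22625 probe sets, and these values are on a log2 scale, judged from their range of 2.62 to 14.04. The method by which the authors summarised and normalized them to these log2 values is not given in the sources used here, and neither is a background correction. Detection calls and scanner files were not analysed here, so background, slide and scan date could not be used as filters or blocks. The medians of the arrays were 5.93, 5.91 and 5.91 for wild-type replicates 1 to 3 and 5.97, 5.95 and 5.95 for the mutant ones. In place of detection calls, 32 control probe sets for bacterial and yeast transcripts that are not spiked in gave a background level: their values had a median of 3.45, and 95% lay at or below 5.05. The processing can affect the measurements, since unspecific signal can compress log2 differences of dim probe sets toward 0. Whether it did so here is unknown, because the background correction is not known.

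Probe sets were named through the platform's annotation table, with symbols updated by Entrez ID from a RefSeq gene table of assembly WBcel235. That table was used for names and for the order of neighbouring genes only. After 77 control probe sets were left out, 22548 were tested. Of these, 20766 had 1 gene, 887 had several and 895 had none listed, and 20701 of those with 1 gene were matched by Entrez ID. By their type, 6711 of the tested probe sets can read several transcripts. They include those used for hyl-1, hsp-4, cyp-14A5, icl-1, act-5, cpr-3 and cut-2, among others, whose signals may not be theirs alone. A gene was represented by its probe set with the highest mean over the 6 arrays among probe sets annotated to that gene alone, which gave 17118 genes, of which 2981 had more than 1 probe set. Among the genes called, 67 had several probe sets; 6 of these had a probe set of the opposite sign, in 0 of them past the threshold, and none of the 6 is named here.

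The mutant was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), on the deposited log2 values without further normalization or a filter on dim probe sets, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are mutant minus wild type. In tests on simulated data with 17118 genes, 3 arrays against 3 and 200 changed genes, 61.8% of genes changed by 1 on the log2 scale and 91.4% of those changed by 2 were recovered, and 3.89% of calls were false. The simulated noise was independent between genes and arrays, unlike that of the real arrays, so these shares need not hold for the real calls. Gene lists, 51 in all, were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and their members were counted as called over all genes and when adjusted over the list alone. Some lists share genes.

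Genes were named by a rule set before the data were examined. It takes hyl-1, lagr-1, hyl-2, daf-16, daf-2 and 1 further gene that is not reported here. It adds the 10 largest increases and the 10 largest decreases among called genes whose arrays do not overlap between genotypes, up to 4 members of each list with the smallest unadjusted p, and every called member of a list with at most 5 calls.

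Replicate numbers are the same in both genotypes, and whether they pair the arrays was checked before the fits were compared. Deviations from the group means, across genes, correlated at 0.377, 0.449 and 0.4 between arrays with the same number in different genotypes, and between -0.353 and 0.0872 for different numbers. The numbers were therefore taken to pair the arrays. The pairing comes from the data, since the labels name no shared day or batch. The fit without the block is reported, as planned. The value with the replicate block stands beside a result where it changes the call or moves a count by over 1.5 times. It is also given for some genes that lose the call in a fit without a single array. Those fits leave out the block too, so a shift shared by equal replicate numbers counts as noise in them.

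The alternatives were quantile normalization, median centring, leaving out the dimmest 40% of probe sets, a variance prior without a trend, the replicate block, array weights, leaving out each array in turn, a 2-fold minimum, an adjusted p threshold of 0.01, an ordinary two-sample test with equal variances, the mean over a gene's probe sets, leaving out probe sets that can read several transcripts, camera with an estimated correlation, and fry. Leaving out both replicate 2 arrays was added after seeing the data. Permutation tests of lists used 10000 random lists matched on mean signal. Figures were drawn with matplotlib.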

Results

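RNA was measured in starved Caenorhabditis elegans larvae at L1, the stage that hatches from the egg and halts its growth when no food is present. Wild-type larvae were compared with larvae that carry deletion alleles of hyl-1 and lagr-1, which encode ceramide synthases, the enzymes that join a fatty acid to a sphingoid base. Each genotype had 3 biological replicates, every one on its own Affymetrix C. elegans array, collected 30 h after eggs were freed by bleaching and kept at 20 °C in buffer without food or cholesterol. The array medians were between 5.91 and 5.97 on the log2 scale. Arrays of the same genotype correlated across probe sets at 0.976 or more, and those of different genotypes at between 0.9705 and 0.9843. Spiked hybridisation controls averaged 9.86 on wild-type replicate 2 and between 8.99 and 9.35 on the other arrays. The number of arrays, 6 in all, limits the precision of every value. The comparison asks which transcripts differ in arrested larvae when these ceramide synthase genes are deleted.

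The ceramide synthase genes were examined first, as a check of the labels. hyl-1 signal fell from 7.40 ± 0.26 in wild type to 6.07 ± 0.11 in the mutant (log2, SD, n = 3), a 2.5-fold lower level (log2 difference -1.32 ± 0.18 SE, limma adjusted p = 0.0124). lagr-1 signal was 6.24 ± 0.35 in wild type and 5.36 ± 0.42 in the mutant, a log2 difference of -0.88 ± 0.26 that missed the threshold (adjusted p = 0.119) although all 3 mutant arrays lay below all 3 wild-type arrays. With the replicate number as a block, lagr-1 passed (adjusted p = 0.00953). hyl-2, the third ceramide synthase gene, was at 6.10 ± 0.08 in wild type and 6.11 ± 0.04 in the mutant (log2 difference 0.02 ± 0.14 SE, adjusted p = 0.967). The hyl-1 call was lost without wild-type replicate 1 (adjusted p = 0.0543), mutant replicate 1 (0.0662) or mutant replicate 3 (0.0703). Where the probes lie relative to the deleted segments is not given in the sources used here, and the hyl-1 probe set is of a kind that can read more than a single transcript, so these levels check the labels only in part.

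**Figure D1:**
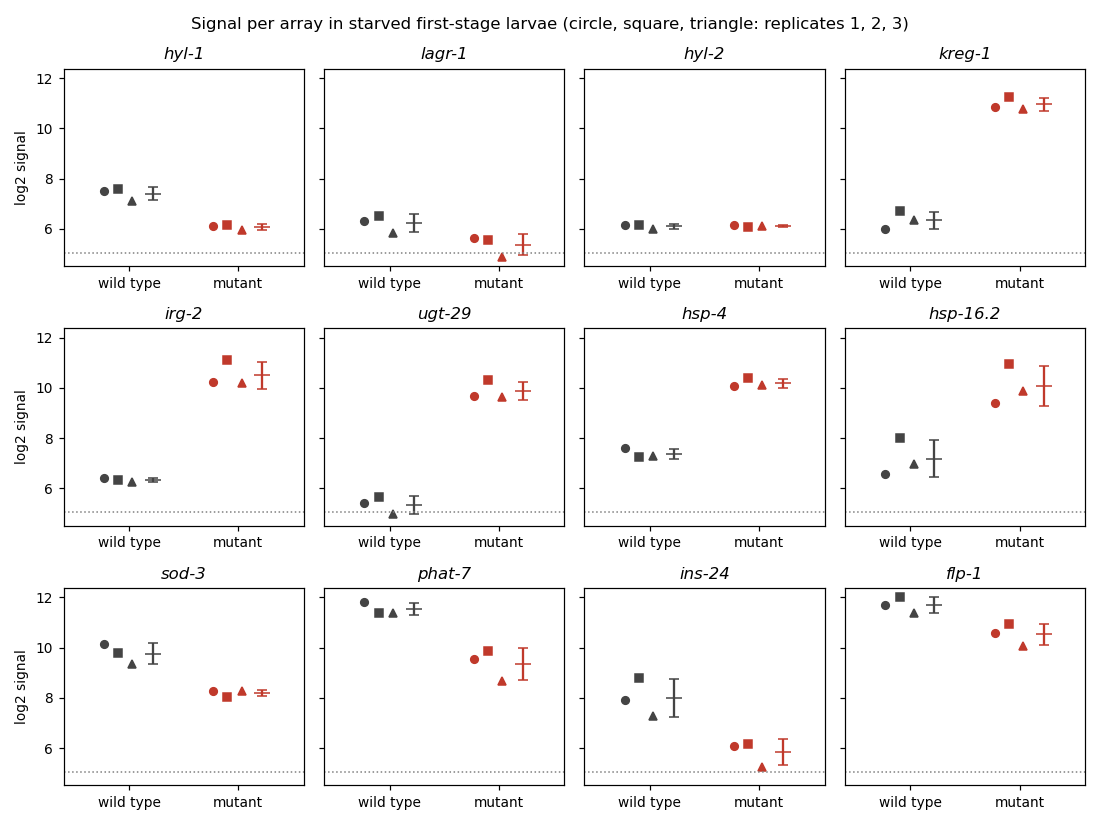
Log2 signal of 12 genes on each of the 6 arrays, with wild type in grey and the hyl-1;lagr-1 mutant in red. Circles, squares and triangles are replicates 1, 2 and 3, the horizontal mark and bar are the mean and SD (n = 3), and the dotted line at 5.05 is the level at or below which 95% of the values of unspiked bacterial and yeast controls lay; kreg-1 rose from 6.35 to 10.96 and hyl-1 fell from 7.40 to 6.07.

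Across the genome, 305 genes were higher and 175 lower in the mutant, out of 17118 tested (limma with Benjamini-Hochberg, adjusted p under 0.05), and 228 of the higher and 83 of the lower genes differed at least 2-fold. The largest increases were in kreg-1 (24.5-fold, log2 difference 4.62 ± 0.22 SE, adjusted p = 0.00015), ugt-29 (22.9-fold), fipr-24 (21.8-fold) and C49G7.10 (21.2-fold). irg-2, an infection-response gene, rose 18.1-fold, from 6.33 ± 0.07 to 10.51 ± 0.54 (log2, SD, n = 3), and srlf-36 rose by a log2 difference of 4.04. fipr-26 (13.6-fold), K09D9.1 (13.5-fold) and srr-6 (13.1-fold) were also among the 10 largest measured increases, as was ugt-28. The probe sets of fipr-24 and fipr-26 can read several transcripts, so these genes may share a signal. The wild-type mean of ugt-28, 4.85, lay below 5.05, the level that 95% of unspiked control values did not exceed, so its fold and rank are not given.

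Decreases were smaller. sshk-1 fell by 2.67 on the log2 scale (6.36-fold lower, SE 0.41, adjusted p = 0.0179), and gst-41, a glutathione S-transferase gene, was 5.59-fold lower. phat-7, a gene of a family of pharyngeal gland proteins, went from 11.53 ± 0.24 to 9.36 ± 0.63 (log2, SD, n = 3), 4.50-fold lower, and ins-24, which encodes an insulin-like peptide, was 4.43-fold lower. F55A4.7, C54D10.3, M04G7.1 and txt-4 had log2 differences of -2.07, -2.0, -1.99 and -1.96, and Y110A2AL.9 and eakr-3 were also among the 10 largest measured decreases. Mutant means of Y110A2AL.9 (4.94) and eakr-3 (4.78) lay below 5.05, so their folds and ranks are not given.

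At the level of probe sets, 348 were higher and 190 lower out of 22548. With the replicate number as a block, 776 genes were higher and 729 lower, and all 480 genes called without the block were among them; for probe sets the blocked counts were 933 and 820. Centring each array on its median gave 293 higher and 257 lower genes, so that 53.3% of the calls were higher against 63.5% as reported, and 329 higher and 275 lower probe sets. The balance turned with array weights (877 higher and 1024 lower genes) and without wild-type replicate 3 (243 and 256), so it is not a stable feature of these data. In the other fits without a single array more calls were higher. The share was 80% and 66.1% without wild-type replicates 1 and 2, and 88.7%, 80.4% and 88.8% without mutant replicates 1, 2 and 3. The count of 480 genes became 160 without wild-type replicate 1, 678 without wild-type replicate 2, 499 without wild-type replicate 3, and 133, 138 and 125 without mutant replicates 1, 2 and 3. The 10 largest increases passed in each of these 6 fits; of the 10 largest decreases, txt-4 did so and the other 9 lost the call in at least 1 fit while keeping their sign. Leaving out both replicate 2 arrays gave 354 higher and 147 lower genes, 324 of them shared with the 480. Of the genes named by the rule, eakr-3, gst-15, gsto-1, daf-7, ceh-22, flp-12, mrps-14, cpt-4, ttr-28, cpl-1, col-89, cut-2, pdi-6, rmd-1 and inf-1 lost the call in that fit, with adjusted p between 0.0553 and 0.127.

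Of 42 infection-response genes measured, 10 rose and 32 did not pass the test; adjusted over the list alone, 15 rose. Beside irg-2, these included clec-67 (3.52-fold), F35E12.10 (2.70-fold) and hpo-6 (4.24-fold). Camera with its preset correlation placed the list above other genes (adjusted p = 1.1e-08), but adjusted p = 0.61 with an estimated correlation. Of 36 secreted antimicrobial peptide genes, 5 rose: fipr-24, fipr-26, cnc-4 (7.06-fold), nlp-25 (4.06-fold) and cnc-6 (3.0-fold). The probe sets of fipr-24 and fipr-26 can read several transcripts, and their mutant means were alike (10.58 and 10.5, log2). Whether these are separate signals was not tested. With members adjusted over the list alone, 5 rose and 2 fell, with the block 7 rose and 3 fell, and the camera call (adjusted p = 0.00502) was lost without wild-type replicate 3 (0.0842) and had adjusted p = 0.81 with an estimated correlation. The lysozyme gene lys-3 rose 4.14-fold, alone among 16 measured lysozyme genes, of which 6 rose when adjusted over the list alone and 5 with the block (camera adjusted p = 0.000111, and adjusted p = 0.61 with an estimated correlation).

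C-type lectin genes went both ways, with 8 higher and 3 lower of 220 measured. clec-67, clec-265 (2.61-fold) and clec-173 (from a wild-type mean below 5.05) rose, and clec-1 fell by 0.93 on the log2 scale. In limma adjusted over the list alone the counts were 11 and 3, and with the block 18 and 4. The camera test gave adjusted p = 0.00348, which was lost without wild-type replicate 1 (0.0509) or wild-type replicate 3 (0.0505), and adjusted p = 0.831 with an estimated correlation. In the pals and intracellular pathogen response list, cul-6, a cullin gene, rose 3.68-fold and skr-3, a Skp1-related gene, rose 1.99-fold, and the other 27 of 29 genes did not pass; adjusted over the list alone, 2 rose (camera adjusted p = 0.674). In this group of defence lists, irg-2, clec-67, clec-265, clec-1, F35E12.10, hpo-6, fipr-24, fipr-26, cnc-4 and nlp-25 passed in each of the 6 fits without a single array, whereas cnc-6, lys-3, clec-173, cul-6 and skr-3 lost the call in at least 1.

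Of 64 measured genes for UDP-glucuronosyltransferases (ugt), which attach sugars to small lipophilic compounds, 10 rose, among them ugt-29, ugt-28, ugt-26 (8.41-fold) and ugt-31, and 54 did not pass. Adjusted over the list alone, 18 rose and 2 fell, and with the block 21 rose and 1 fell. Camera gave adjusted p = 1.1e-08, and adjusted p = 0.61 with an estimated correlation. Of 45 ABC transporter genes, haf-2 (2.90-fold), pgp-5 and wht-1 rose; wild-type means of pgp-5, wht-1 and ugt-31 lay below 5.05, so their folds are not given; adjusted over the list alone 9 rose, and with the block 10. That list's camera call (adjusted p = 0.00623) was lost when probe sets that can read several transcripts were left out (0.169) and had adjusted p = 0.61 with an estimated correlation.

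Among 73 cytochrome P450 genes, cyp-14A5 rose 12.9-fold, from 6.53 ± 0.42 to 10.22 ± 0.25 (log2, SD, n = 3), and cyp-33C8 rose 2.28-fold; adjusted over the list alone 4 rose and 1 fell, and with the block 7 rose and 3 fell (camera adjusted p = 0.512). Of 45 glutathione S-transferase genes, gst-41, gst-15, gst-20 and gsto-1 fell, the last 3 by 0.76, 0.65 and 0.94 on the log2 scale. With members adjusted over the list alone, 3 rose and 10 fell, with the block 3 rose and 7 fell, and camera gave adjusted p = 0.182 over all arrays and 0.867 with an estimated correlation. That list passed camera without both replicate 2 arrays (0.00199), mutant replicate 2 (2.5e-05) or wild-type replicate 3 (0.0118), and with array weights (0.0129). In the SKN-1 and oxidative stress list, sod-3 (a mitochondrial superoxide dismutase), gpx-6 (a glutathione peroxidase) and trxr-2 (a mitochondrial thioredoxin reductase) fell by 1.56, 1.03 and 0.93 on the log2 scale, and 26 of 29 genes did not pass. In limma adjusted over the list alone 5 fell, as did 5 with the block; camera gave adjusted p = 0.269, 0.867 with an estimated correlation, 0.0365 without both replicate 2 arrays and 0.000236 without mutant replicate 2. In these detoxification lists ugt-26, ugt-28, ugt-29, ugt-31, pgp-5 and cyp-14A5 passed in each fit without a single array, and the other genes named lost the call in at least 1 of the 6.

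In the endoplasmic reticulum unfolded protein response list, 5 of 23 measured genes rose. hsp-4, the BiP chaperone that marks the unfolded protein response, rose 6.98-fold, from 7.39 ± 0.20 to 10.19 ± 0.17 (log2, SD, n = 3, adjusted p = 0.000337). Its probe set is of a kind that can read several transcripts. ckb-2, which encodes a choline kinase, rose 9.03-fold, and pdi-2 (2.37-fold), pdi-6 (1.55-fold) and dnj-27 (from a wild-type mean below 5.05), genes of protein folding in that compartment, also rose. The other 18 did not pass; adjusted over the list alone 11 rose, and with the block 9. The camera test gave adjusted p = 1.74e-07, and adjusted p = 0.61 with an estimated correlation. Among 20 cytosolic heat shock genes, hsp-16.2 rose 7.35-fold and hsp-12.3 fell by 0.83 on the log2 scale; adjusted over the list alone 4 rose and 3 fell, and with the block 3 rose and 1 fell. The camera test of this list missed the threshold (adjusted p = 0.216, and 0.61 with an estimated correlation) and passed it with the block (0.0434). None of 15 genes of the mitochondrial chaperone and unfolded protein response list passed in limma, adjusted over all genes or adjusted over the list alone; 3 higher and 1 lower had unadjusted p under 0.05 (camera adjusted p = 0.536). hsp-4 and ckb-2 passed in each fit without a single array. dnj-27, pdi-2, pdi-6, hsp-16.2 and hsp-12.3 lost the call in at least 1 of the 6, which leave out the replicate block. With the block over all arrays each of these genes passed. The SE of hsp-16.2 was then 0.14 against 0.46 without the block (limma adjusted p = 3.99e-05).

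Insulin signalling, through which food and starvation act on the transcription factor DAF-16, was examined through its components, ligands and targets. daf-16 was at 10.25 ± 0.16 in wild type and 9.96 ± 0.21 in the mutant (log2, SD, n = 3, adjusted p = 0.36), while both means of the insulin receptor gene daf-2 (4.34 and 4.28) lay below 5.05, so its level cannot be compared here. None of the 18 signalling components passed in limma, adjusted over all genes or adjusted over the list alone, and akt-1 had the smallest unadjusted p, 0.0244, with a log2 difference of -0.38 (camera adjusted p = 0.844). Of 24 insulin-like peptide genes, ins-24 and ins-30 fell by 2.15 and 1.52 on the log2 scale; both are among the 7 called genes within 50 genes of hyl-1 or lagr-1, so a linked strain difference is not excluded for them; adjusted over the list alone 2 fell, and with the block 1 rose and 5 fell. Camera gave adjusted p = 0.215 for these peptides, 0.831 with an estimated correlation and 0.0223 without wild-type replicate 3. daf-7, the TGF-beta ligand that controls dauer entry, fell by 1.24 and was the single call among 25 TGF-beta and dauer genes (camera adjusted p = 0.581); adjusted over the list alone 1 rose and 3 fell, and with the block 1 rose and 2 fell. daf-7 is made in sensory neurons, and neuron markers had a median log2 difference of -0.35 in the same comparison.

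Genes known to be raised by DAF-16 split, with 2 of 25 higher and 4 lower. sod-3 and hsp-12.3 fell, and hsp-16.2 and icl-1, the glyoxylate cycle enzyme gene, rose, icl-1 by 3.90-fold. Adjusted over the list alone 3 rose and 7 fell, and camera gave adjusted p = 0.429, with a median of -0.09 and a mean of 0.13. Among 20 genes known to be lowered by DAF-16, dod-19 rose 4.06-fold; adjusted over the list alone 4 rose, as did 4 with the block. Camera placed this list higher (adjusted p = 0.000431), with adjusted p = 0.61 with an estimated correlation, and 12 of its 20 genes also stand in other lists. In these signalling lists icl-1 passed in each fit without a single array, and ins-24, ins-30, daf-7, sod-3, hsp-12.3, hsp-16.2 and dod-19 lost the call in at least 1 of the 6.

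Metabolic lists held few calls. cpt-4, of the carnitine palmitoyltransferase family, rose from a wild-type mean below 5.05 and acox-1.1, an acyl-CoA oxidase gene, rose 2.32-fold among 40 beta-oxidation genes; adjusted over the list alone 7 rose, and with the block 6. The camera test gave adjusted p = 0.00238, and adjusted p = 0.61 with an estimated correlation. icl-1 and cpt-4 were the 2 calls among 26 fasting and lipid mobilisation genes (3 when adjusted over the list alone, 5 higher and 1 lower with the block, camera adjusted p = 0.275), and icl-1 and hxk-1, a hexokinase gene raised 2.07-fold, those among 26 trehalose, glycogen and gluconeogenesis genes (4 when adjusted over the list alone, 5 higher and 1 lower with the block, camera adjusted p = 0.663). Of 30 genes of fatty acid desaturation, elongation and synthesis, none passed in limma, adjusted over all genes or adjusted over the list alone, 5 higher and 2 lower had unadjusted p under 0.05, and 3 rose with the block (camera adjusted p = 0.293). In the sphingolipid metabolism list, 0 of 22 genes passed over all genes, with 3 higher and 1 lower at unadjusted p under 0.05. With members adjusted over the list alone, sptl-3, a serine palmitoyltransferase subunit gene, rose (log2 difference 0.98 ± 0.22 SE) and asm-3, an acid sphingomyelinase gene, fell (-0.97 ± 0.22 SE), and with the block both passed over all genes (adjusted p = 0.00707 and 0.0051; camera adjusted p = 0.74). cpt-4, acox-1.1 and hxk-1 each lost the call in at least 1 of the 6 fits without a single array.

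Protein degradation genes included 5 raised cathepsins, cpr-1, cpr-2, cpr-3, cpr-4 and cpl-1, among 48 lysosomal protease and vacuolar ATPase genes. cpr-4 rose most, 4.77-fold, and cpr-2 rose from 10.84 ± 0.29 to 12.17 ± 0.25 (log2, SD, n = 3). In limma adjusted over the list alone 6 rose and 1 fell, and camera gave adjusted p = 0.443. cpr-4 and cpr-1 also stand among the 25 intestine markers, of which 6 rose, including gem-4 (2.78-fold) and act-5, the actin of intestinal microvilli (2.79-fold). Adjusted over the list alone 10 intestine markers rose and 1 fell. Camera gave adjusted p = 0.00134 for the intestine list, lost without wild-type replicate 2 (0.0649), and adjusted p = 0.61 with an estimated correlation. cpr-4 and gem-4 passed in each fit without a single array, and cpr-1, cpr-2, cpr-3, cpl-1 and act-5 lost the call in at least 1 of the 6.

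Among 53 neuron markers, 3 fell. The FMRFamide-like peptide genes flp-1, flp-2 and flp-12 fell by 1.18, 1.05 and 0.94 on the log2 scale, the other 50 did not pass, and 44 of the 53 had negative log2 differences. With members adjusted over the list alone 18 fell and 1 rose, and with the block 15 fell and 1 rose. The camera test gave adjusted p = 1.57e-08, and adjusted p = 0.61 with an estimated correlation. Among pharynx markers, phat-6, phat-3 and ceh-22, an NK-2 homeobox gene of pharyngeal muscle, fell by 1.75, 1.1 and 0.78, and 20 of 23 did not pass. In limma adjusted over the list alone 6 fell and 1 rose, with the block 6 fell, and without both replicate 2 arrays 7 fell and 1 rose. Camera gave adjusted p = 0.00435 for the pharynx list, and adjusted p = 0.61 with an estimated correlation. Each of these 6 genes lost the call in at least 5 of the 6 fits without a single array while keeping its sign. With the replicate block over all arrays each of them passed. flp-1, flp-2 and flp-12 then had limma adjusted p = 0.00079, 0.0023 and 0.0034.

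Body wall muscle and hypodermis markers gave no calls in limma, adjusted over all genes or adjusted over the list alone. Of 29 muscle markers, 5 had unadjusted p under 0.05, all higher (camera adjusted p = 0.191), and of 25 hypodermis markers, 2 were higher and 1 lower at that level (camera adjusted p = 0.191). With the block 1 muscle marker, dim-1, rose and 1 hypodermis marker, dpy-5, fell. Without wild-type replicate 3 camera passed both lists (adjusted p = 0.0223 for muscle and 0.0322 for hypodermis). It also passed muscle without wild-type replicate 1 (0.0263) and hypodermis without mutant replicate 2 (0.0135). Without both replicate 2 arrays camera gave adjusted p = 0.723 for muscle and 0.398 for hypodermis, and with an estimated correlation 0.831 for both. Relative to the mean of all arrays, muscle marker means were 0.0698, -0.48 and 0.161 on wild-type replicates 1 to 3. On mutant replicates 1 to 3 they were 0.0866, 0.0613 and 0.101, so the higher mutant mean rests on wild-type replicate 2. Median log2 differences were 0.18 for muscle, 0.14 for hypodermis, 0.10 for intestine, -0.31 for pharynx and -0.35 for neurons.

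Of 22 oocyte, eggshell and yolk genes, 2 rose. These were cpg-3, a chondroitin proteoglycan gene (2.23-fold), and rmd-1, which encodes a regulator of microtubule dynamics (2.56-fold). Adjusted over the list alone 11 rose, and with the block 6; camera gave adjusted p = 8.15e-07, and adjusted p = 0.61 with an estimated correlation. Among 43 germline and P granule genes none passed in limma, adjusted over all genes or adjusted over the list alone, 8 had unadjusted p under 0.05, all higher, and 4 rose with the block. gld-1 and prg-1 had log2 differences of 1.28 and 1.02 without passing, and passed with the block (adjusted p = 0.0252 and 0.0268), and camera gave adjusted p = 9.09e-06 for the list and adjusted p = 0.61 with an estimated correlation. Sperm genes (74), small RNA pathway genes (54), embryonic specification genes (24) and cell cycle and DNA replication genes (41) held 0 calls over all genes or adjusted over the list alone; limma gave 4, 11, 2 and 2 of them an unadjusted p under 0.05, the block called 1, 4, 2 and 0, and camera gave adjusted p = 0.527, 0.361, 0.536 and 0.526. Camera passed the small RNA list without wild-type replicate 3 (adjusted p = 0.0105) and the cell cycle list without mutant replicate 2 (0.0184); with an estimated correlation they had adjusted p = 0.883 and 0.904. cpg-3 and rmd-1 lost the call in at least 1 of the 6 fits without a single array.

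**Figure D2:**
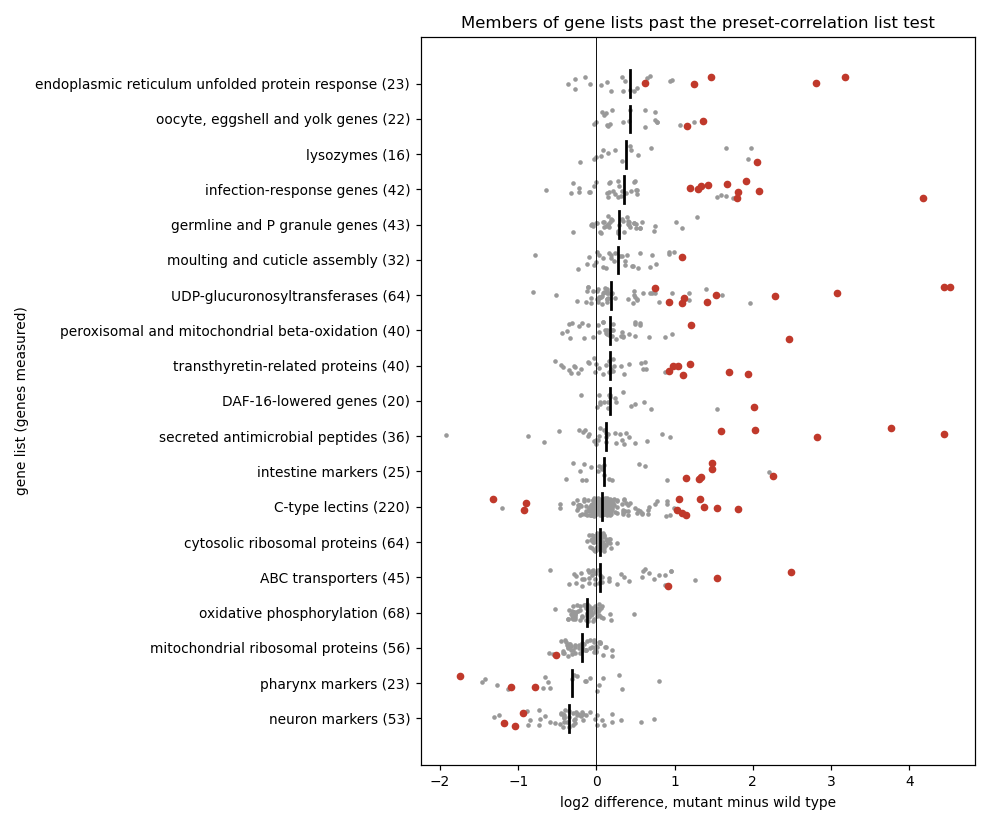
Log2 difference, mutant minus wild type, of every measured gene in 19 gene lists past the camera test with its preset correlation (ceramide synthases left out), with the number of genes measured after each name. Red points are genes past the limma test, grey points are the others, black bars are list medians, and vertical scatter within a list has no meaning; the median was 0.43 in the endoplasmic reticulum unfolded protein response list and -0.35 in the neuron markers.

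Of 147 collagen-list genes, col-89 rose 1.67-fold and dpy-18, a prolyl 4-hydroxylase subunit gene and not itself a collagen, rose 3.77-fold; adjusted over the list alone 1 rose, with the block 7 rose and 4 fell, and camera gave adjusted p = 0.857. Among 32 moulting and cuticle assembly genes, the cuticlin gene cut-2 rose 2.14-fold. With members adjusted over the list alone 2 rose and 1 fell, and with the block 3 rose and 1 fell; camera gave adjusted p = 0.0022, and adjusted p = 0.61 with an estimated correlation. Transthyretin-related genes, a nematode family of secreted proteins, had 7 of 40 higher, with ttr-26 (3.23-fold), ttr-6 (2.29-fold), ttr-32 (2.07-fold) and ttr-28 among them, the last from a wild-type mean below 5.05. In limma adjusted over the list alone 9 rose and 2 fell, and with the block 11 rose; camera gave adjusted p = 0.00623, lost without wild-type replicate 3 (0.286), and adjusted p = 0.831 with an estimated correlation. All of the genes named here lost the call in at least 1 of the 6 fits without a single array.

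Regulatory families gave scattered calls. Of 254 nuclear hormone receptor genes 5 rose, among them nhr-147 (3.14-fold), nhr-112 (2.43-fold) and nhr-63 (2.41-fold), and nhr-216 fell, to a mutant mean below 5.05. Adjusted over the list alone the counts were also 5 and 1, and with the block 11 and 7 (camera adjusted p = 0.698). Of 395 genes of the F-box and MATH-domain families 7 rose, among them fbxc-58 (10.1-fold), fbxa-79 (2.33-fold), and fbxa-163 and fbxa-36 from wild-type means below 5.05; adjusted over the list alone 7 rose, and with the block 12 rose and 6 fell (camera adjusted p = 0.512). hil-1, a linker histone gene, fell by 0.83 and was the single call among 34 histone genes, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.217). nhr-112, nhr-216, fbxc-58, fbxa-163 and fbxa-36 passed in each fit without a single array, and nhr-147, nhr-63, fbxa-79 and hil-1 lost the call in at least 1 of the 6.

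Of 56 mitochondrial ribosomal protein genes, mrps-14 fell by 0.52, also when adjusted over the list alone, and 46 had negative differences, with a median of -0.19 (camera adjusted p = 0.000218, and adjusted p = 0.733 with an estimated correlation). None of 68 oxidative phosphorylation genes passed in limma, adjusted over all genes or adjusted over the list alone; 13 lower and 1 higher had unadjusted p under 0.05, with a median of -0.12. Its camera call (adjusted p = 0.00146) was lost with quantile normalization (0.0884) and had adjusted p = 0.81 with an estimated correlation. Of 64 cytosolic ribosomal protein genes 0 passed in limma, adjusted over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The camera call of that list (adjusted p = 0.0193) had adjusted p = 0.61 with an estimated correlation and was lost with the block (0.103), median centring (0.277), quantile normalization (0.0518) or a variance prior without a trend (0.117), without probe sets that can read several transcripts (0.0721), and without mutant replicate 1 (0.148) or 3 (0.0675). inf-1, an initiation factor eIF4A gene, rose 2.5-fold, alone among 37 translation factors (1 when adjusted over the list alone, camera adjusted p = 0.191, 0.81 with an estimated correlation and 0.049 without both replicate 2 arrays). mrps-14 and inf-1 lost the call in at least 1 of the 6 fits without a single array.

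Apart from the ceramide synthases, where hyl-1 fell, the remaining lists held 0 calls over all genes in limma. Saposin-like protein genes (18, of which 1 fell when adjusted over the list alone), proteasome subunits (33), autophagy genes (29), apoptosis and engulfment genes (22) and Rb and synMuv class B genes (22) had 4, 2, 3, 0 and 1 members at unadjusted p under 0.05, and the last 4 had 0 calls when adjusted over the list alone. With the block 2 saposin-like and 2 autophagy genes fell. Camera gave these lists adjusted p = 0.251, 0.536, 0.536, 0.74 and 0.822. The 3 ceramide synthase genes as a list had a camera adjusted p of 0.0364, which was 0.61 as an adjusted p with an estimated correlation and was lost without wild-type replicate 1 (0.0683), wild-type replicate 2 (0.0723), mutant replicate 3 (0.0597), both replicate 2 arrays (0.0723) or the dimmest 40% of probe sets (0.105); adjusted over the list alone 2 fell, as did 2 with the block. Median, mean and camera direction differed in sign for the DAF-16-raised, SKN-1 and oxidative stress, trehalose and gluconeogenesis, and pals lists, of which camera passed none. Without both replicate 2 arrays, 4 lysozyme, 3 DAF-16-lowered, 2 moulting, 2 fatty acid synthesis, 1 hypodermis and 1 oocyte gene rose, and 5 cytochrome P450 genes rose and 1 fell.

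Camera with the preset correlation passed 20 of the 51 lists. All 20 calls were lost with an estimated correlation, where the smallest adjusted p was 0.61, a tied value that many lists share. The 3 lists with an unadjusted camera p under 0.05 there were intestine markers (0.0288), oocyte, eggshell and yolk genes (0.0325) and pharynx markers (0.0453). Estimated correlations of the intestine and pharynx lists, 0.02 and 0.0242, lay near the preset 0.01. A larger correlation need not be the whole cause of the loss, which was not tested. fry, which tests whether a list's genes move one way on balance, passed 0 lists, with a smallest adjusted p of 0.0684 and 13 lists at unadjusted p under 0.05. For changes in either direction it passed 34. Neither fry nor camera with an estimated correlation was run with the replicate block. The mean over members lay apart between the genotypes on all arrays for 15 of the 20 lists. Over all 51 lists it did so for 21, against 10% by chance for any single list. Camera picked the 20 on the same difference, lists are not independent, and 25.4% of all genes tested also lay apart. An exact permutation test of such a mean with 3 arrays against 3 cannot give a p below 0.1. Regrouping the 6 arrays across genotypes also passed between 9 and 23 lists; the 2 regroupings above 20 part only 1 pair of equal replicate number, and the 4 splits that part all 3 pairs passed 20 (the real one), 15, 17 and 9.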

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

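Leaving out both replicate 2 arrays was chosen after seeing the data. The counts of 538 probe sets and 480 genes became 1753 and 1505 with the replicate block, 2206 and 1901 with array weights, 356 and 311 with a 2-fold minimum, and 117 and 100 at an adjusted p of 0.01. An ordinary two-sample test called 0 of either (smallest adjusted p 0.0743 for probe sets and 0.0636 for genes), with 3534 probe sets and 2783 genes at unadjusted p under 0.05. The stricter thresholds lower the counts by construction, and for the block, the weights and the ordinary test the cause was not tested. Leaving out a single array gave 134 to 766 probe sets and 125 to 678 genes. hyl-1 stayed lower in these fits, with log2 differences from -1.47 to -1.23, and lost the call in 3 of them. lagr-1 gained a call with the replicate block (-0.88, adjusted p = 0.00953) and with array weights (-0.93, adjusted p = 0.0425), and had adjusted p between 0.0808 and 0.317 under the other 11 alternatives. The count of 20 lists became 0 with an estimated inter-gene correlation and 0 with fry, and lay between 17 and 24 under the other alternatives.

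Quantile normalization kept 441 of the 480 genes, median centring 465, the variance prior without a trend 435, and the block and the weights all 480. Leaving out probe sets that can read several transcripts kept 353 of the 371 still measured and moved 1 called gene to the other sign. Scaling moved the median log2 difference of all genes by at most 0.04 in size (-0.04 with centring and -0.02 with quantile normalization). For the 206 other named genes and the 51 lists, 3041 values under alternatives stayed on the same side of the threshold, 317 lost and 174 gained a call, and 0 of these changed the direction of a call. All 93 named genes past the threshold kept their sign in the 6 fits without a single array, and 32 stayed past it in every one, 29 higher and 3 lower. The replicate block changed no other list call than those given in the results. Alternatives with another log offset were not run, since the values are on a log2 scale. Signal over background limits dim genes: the lower quartile of mean gene signal, 4.32, lies below 5.05.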

Other observations

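The genes named in this part outside the rule were chosen after their values were seen, as were the scan of gene-name families and the tests on neuron markers and on oocyte and germline genes; the tests on neighbouring genes and on regrouped arrays were written before their results. A scan of all 165 gene-name families with at least 10 genes tested, in both directions (330 Fisher exact tests, one-sided, Benjamini-Hochberg), passed the ugt (10 of 64, 1.14 by chance, adjusted p = 5.94e-05) and ttr families (7 of 40, 0.713 by chance, adjusted p = 0.000989) for increases and the nlp family of neuropeptide-like genes for decreases (5 of 58, 0.593 by chance, adjusted p = 0.0343). The 5 nlp genes were nlp-18, nlp-52, nlp-60 (within 50 genes of hyl-1 or lagr-1), nlp-69 and nlp-80; nlp-25 of the same family rose. Each of the 5 passed in 2 or fewer of the 6 fits without a single array, and without both replicate 2 arrays nlp-52, nlp-60 and nlp-69 lost the call (adjusted p = 0.0661, 0.0832 and 0.0758). Genes are not independent replicates in such a test. Among single genes in limma, odr-10, the diacetyl receptor gene, fell by 1.53 on the log2 scale (adjusted p = 0.0479), gcy-8, a guanylyl cyclase gene of thermosensory neurons, fell by 1.48, and the homeobox gene ceh-36 fell by 0.93. The cilium gene che-13 fell by 0.75, and the cilium genes dyf-1 and bbs-9 fell to mutant means below 5.05. Each of these 6 genes lost the call in at least 4 of the 6 fits without a single array, and the scan gave no enrichment of decreases in the gcy (3 of 32, adjusted p = 0.198), che (1 of 10, adjusted p = 1) or dyf family (1 of 12, adjusted p = 1).

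odc-1, the ornithine decarboxylase gene, rose 6.37-fold (from 8.51 to 11.18, log2, limma adjusted p = 0.00287). smd-1, the S-adenosylmethionine decarboxylase gene, rose 2.39-fold and is among the 7 called genes within 50 genes of hyl-1 or lagr-1. rop-1, which encodes the Ro RNA-binding protein, rose 6.84-fold to 12.34, and ptr-22, of the patched-related family, rose 7.48-fold. irg-8, an infection-response gene outside the fixed list, rose from a wild-type mean below 5.05. Among regulators, the bZIP gene zip-10 rose 4.67-fold and pqm-1, a zinc finger gene, 1.73-fold. cert-1, which encodes a ceramide transfer protein, fell by 0.60 (adjusted p = 0.0463). odc-1, rop-1, ptr-22 and irg-8 passed in each of the 6 fits without a single array, and smd-1, zip-10, pqm-1 and cert-1 in 2 or fewer. Without both replicate 2 arrays ceh-36, che-13, bbs-9, dyf-1, pqm-1 and cert-1 lost the call, with adjusted p of 0.0523, 0.0694, 0.0623, 0.059, 0.071 and 0.0661.

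Neuron markers had a median log2 difference of -0.35. A dependence of differences on signal level is argued against by matched lists: the neuron median lay at percentile 0 of 10000 random lists of the same size and mean signal. The replicate 2 arrays, with the highest hybridisation control signal, are argued against as the whole cause by the neuron marker means on the other arrays. Relative to the mean of all arrays, these were 0.192 and 0.0343 on wild-type replicates 1 and 3. On mutant replicates 1 and 3 they were -0.224 and -0.268. The camera call also held without the replicate 2 arrays (adjusted p = 2.28e-09). Over 17 alternatives its adjusted p ranged from 5.85e-10 to 0.61, and the 15 that kept the preset correlation gave at most 1.34e-05. Camera with that correlation also passed between 9 and 23 lists on arrays regrouped across genotypes, so its p cannot decide this. A smaller share of neuronal RNA that raises all other tissues alike is argued against by pharynx markers, whose median lay at -0.486 relative to body wall muscle markers (permuting markers between the lists, permutation p = 1e-05, the smallest that 100000 permutations can give; markers are not independent replicates). Low muscle markers on wild-type replicate 2 (-0.48 relative to the mean of all arrays) widen that gap. The pharynx mean minus the muscle mean still lay apart between the genotypes on all arrays. It was 0.325 ± 0.232 in wild type and -0.325 ± 0.193 in the mutant (log2, SD, n = 3). Pharynx markers were lower too (median -0.31), so a smaller share of both neuronal and pharyngeal RNA is not argued against. Lower transcript levels of neuronal genes in the mutant remain a hypothesis, found and tested on the same data. Scan date, slide and the shares of tissues stay open.

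Oocyte, eggshell and yolk genes had a median log2 difference of 0.43 and germline genes one of 0.29. One candidate explanation is a larger share of unhatched or younger embryos in the mutant samples. Markers of embryonic specification had a median at percentile 46.91 of 10000 random lists of the same size and mean signal, which neither shows such a share nor excludes it, because those genes act early in embryogenesis and older embryos need not hold them. A later arrest, a different hatching time and an effect of the genotype on these genes cannot be told apart with these arrays.

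Called genes lay beside one another more often than chance gives: of 479 called genes with a position, 104 had a called gene of the same direction within 3 genes, against 41.2 on average in 10000 permutations (p = 1e-04, the smallest they can give). Clusters included ugt-26, ugt-28 and ugt-25, as well as K09D9.1, C49G7.12, C49G7.10 and irg-2. Chromosome segments carried along with the deletion alleles were examined only within 50 genes on either side of hyl-1 and of lagr-1. Calls were not clearly more frequent there: 7 of 200 flanking genes, ins-24, ins-30, smd-1 and nlp-60 among them (3.5% against 2.79% elsewhere, Fisher exact p = 0.513). Without the flanking genes 102 remained against 40.6 by chance, but so few flanking calls could not have removed the excess. Longer carried segments were not tested. Probe sets that read several related transcripts are argued against as the whole cause, since 64 remained against 28.6 by chance when such probe sets were left out. Shared regulation of neighbouring genes is a hypothesis for the excess, and other strain differences between the genotypes were not tested.

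The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes the genotypes, so genotype differences widen the spread within its groups and lower its probe set and gene counts. For probe sets, 1 of the 10 splits, the real one, gave 538 calls and the highest of the others 0; for genes, 1 of the 10 gave 480 and the highest of the others 0. The 4 splits that part all 3 pairs of equal replicate number gave 480 genes for the real one and 0 for the others, and 20 gene lists for the real one and 15, 17 and 9 for the others. Over all 10 splits, 3 passed at least 20 lists, the real one included, and the highest of the others, which parts only 1 pair, passed 23.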
